A study of Mus musculus with 40 samples.

How the data were processed

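The data are 40 Illumina bead arrays, 1 per RNA sample, from primary embryonic fibroblasts of C57BL/6 mice. Per the labels' protocols, total RNA was taken with a column kit and labelled as biotinylated cRNA. The signal of each probe is a deposited intensity on a linear scale, which per the submitters' processing notes came from Illumina BeadStudio; its version and settings are not given in the sources used here. The intensities are neither background-subtracted nor normalized between arrays, as their values show. Beside each intensity stands a deposited detection p-value, which per the file headers rates the probe against the array's negative controls. A second table holds intensities that the authors normalized between arrays. Its scale is linear, as a rank comparison with the first table showed, and its method and centring are not given in the sources used here. Its column medians were 64.2 to 67.3 on 34 arrays and 47.1 to 47.3 on the 6 arrays of the WT IFNb course, which had been normalized apart, so this table was used only as an alternative and only for the 34 arrays. Columns were tied to samples through the header lines that pair each sample with its column number, and 0 columns of per-sample values were left unused.

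Intensities were background-corrected, quantile-normalized and put on a log2 scale with the neqc procedure of limma 3.58.1 (its nec and normalizeBetweenArrays functions) in R 4.3.3, with an offset of 16 and with negative controls inferred from the deposited detection p-values. Of 24613 probes, 12865 had a detection p under 0.01 on at least 2 arrays. Gene symbols came from a table of the platform's annotation, updated through gene identifiers: 20974 probes had 1 gene, 1 had several and 3638 had none there. Of the symbols, 20958 were updated by Entrez identifier, 8 by accession, and 9 were kept. A gene was represented by its brightest detected probe, which left 9180 genes; 1730 of them had several tested probes. No genome was used, so no positions are given.

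Samples were grouped by genotype, agent and time as the labels give them, in 35 groups. One limma model with a coefficient per group was fitted over all arrays, so that every comparison shares 1 estimate of the spread, with 5 residual degrees of freedom from unstimulated arrays (median residual SD 0.395, prior SD 0.378 with 3.6 prior degrees of freedom, all on the log2 scale). Each response was tested with a moderated F-test over its times against the unstimulated arrays of its genotype. Differences between genotypes were tested as interactions, IFNb followed by TNF against TNF alone at the same time, actinomycin D against its 0 h array, and unstimulated knockouts against WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with its direction taken at the time of the largest change. The ± values are standard errors. No change of fold size was required of a call, and "2-fold" refers to a log2 change of 1.

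The analysis used 21 gene lists. Of these, 13 describe responses: NF-κB targets, interferon-stimulated genes, early genes associated with IRF3, immediate-early and growth-factor genes, cholesterol synthesis, cell cycle, extracellular matrix, MHC class I presentation, the unfolded protein and ATF4 response, p53 targets, short-lived transcripts with AU-rich elements, glycolysis and ribosomal proteins. The others are markers of leukocytes and of endothelial, epithelial, muscle, neural and adipose cells, sex-linked genes and the targeted genes. They were written from general knowledge, some genes stand in several of them, and several NF-κB and interferon genes are also expressed by leukocytes. Response lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list moves on balance; the 429 tests were adjusted as 1 family. No list past camera had a median, mean and test of different sign.

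The genes named were set by a rule. For each comparison and time these are up to 5 highest and 3 lowest genes past the F-test with a log2 change of at least 1 and detected in the brighter group, and for each list up to 4 members with the largest change at the time of the largest list median, together with the targeted genes. A list gene named in one comparison could be named in another. The overlap of LPS with other agents used 100 simulations of unchanged groups against the shared unstimulated arrays.

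The fit was tested on simulated data with the real design and known changed genes (67, 67 and 66 at the 3 sizes). Of genes changed by a log2 of 1, 2 and 4, it recovered 1.5%, 61.2% and 100% for the WT LPS response, 0%, 9% and 87.9% for the crel-/-p65-/- difference in LPS response, 0%, 6% and 83.3% for the crel-/-p65-/-relb-/- difference in TNF response, 1.5%, 23.9% and 92.4% for actinomycin D, and 9%, 86.6% and 98.5% for unstimulated crel-/-p65-/-relb-/- cells. False calls made up 6.9%, 5.9%, 9.2%, 3.7% and 5.8% of calls. Interactions of lone arrays therefore show large changes only. With the unstimulated array of the same course as baseline, recovery was 0%, 6% and 87.9% for the WT LPS response. It was 0%, 0% and 0% for the crel-/-p65-/- difference in LPS response. For the crel-/-p65-/-relb-/- difference in TNF response it was 0%, 0% and 30.3%. A lower count with that baseline can therefore reflect lost power. The simulated noise was independent between arrays, with no shift shared within a course. These rates therefore do not cover differences between courses.

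The settings varied, chosen before the values were seen, were no background correction, scaling to the 75th percentile, the authors' values, no filter on dim probes (15964 genes), probes detected on at least 10 arrays (7761 genes), every probe by itself, trend and robust variances, the unstimulated array of the same course as baseline, course as a block (2 residual degrees of freedom), the array after 3 h of LPS and 0 h of actinomycin D joined with the WT LPS 3 h array, and leaving out each unstimulated array in turn. Alternatives chosen after seeing the data were the spread of an additive fit (13 residual degrees of freedom) with own-course baselines, leaving out the 6 arrays of the WT IFNb course, leaving out genes correlated with leukocyte markers, and the comparison of the 2 knockouts that lack c-Rel and RelA with and without IRF3. The additive fit gives each agent and time the same effect in all genotypes, so real differences between genotypes enter its spread. Course as a block means the agent of the course, so all genotypes under the same agent shared a block. The actinomycin D arrays stood in the LPS block, and the arrays of IFNb then TNF in the IFNb block. Such a block cannot adjust for differences between the courses of different genotypes under the same agent. Slide could not be used as a block, since the column names give none. No groups of 3 against 3 arrays exist, so no regrouping of samples was counted. Probes without a gene in the annotation table were left out of the main comparisons.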

Results

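Gene expression was measured on 40 Illumina bead arrays, one per RNA sample, from primary mouse embryonic fibroblasts. The cells had been left unstimulated or had received bacterial lipopolysaccharide (LPS), the cytokine tumour necrosis factor (TNF), the growth factor PDGFb or the antiviral cytokine interferon beta (IFNb). The cells were of 5 kinds: wild type (WT), cells lacking the NF-κB subunits c-Rel and RelA (crel-/-p65-/-), the same cells lacking also RelB (crel-/-p65-/-relb-/-) or also the transcription factor IRF3 (crel-/-p65-/-irf3-/-), and cells lacking the receptor for type I interferon (ifnar-/-). The unstimulated groups held 4 WT arrays, 2 crel-/-p65-/- arrays, 2 crel-/-p65-/-relb-/- arrays, 1 crel-/-p65-/-irf3-/- array and 1 ifnar-/- array. Each stimulated condition, at 1, 3 or 8 h, was 1 array. In WT cells, all 4 agents had 3 times each, a further pair of arrays received TNF for 3 or 8 h after 2 h of IFNb, and 3 arrays followed actinomycin D for 0, 1 or 3 h after 3 h of LPS. The series title poses the question of how the NF-κB, IRF3 and interferon signals of a pathogen response are combined, at the same time or in succession.

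The summed signal of an array lay between 5.27e6 and 6.06e6 in the WT IFNb course, between 6.88e6 and 7.61e6 in the crel-/-p65-/-irf3-/- course, and between 9.64e6 and 1.62e7 on the other arrays. Between 7703 and 11984 probes were detected per array. For arrays, it is their number that limits precision: 9180 genes were tested with 5 residual degrees of freedom, which came only from unstimulated arrays. The p-values therefore measure the spread between those arrays, which the labels do not describe as separate cultures, and every lone array is assumed to vary like them. Of the 40 arrays, 38 correlated best with another array of their own course (one agent in one genotype), with a median correlation of 0.981 within courses and 0.922 between courses. The 4 unstimulated WT arrays, each from another course, correlated at 0.963 at most. Course and agent coincide for stimulated arrays, so a count that moved by more than 1.5 times with the unstimulated array of the same course as the baseline is also given that way. The groups, tests, gene lists and the rule for naming genes were fixed before the data were examined. Genes not detected on one side of a comparison have only a lower bound on their fold, written as at least N-fold. The bound is the brighter level over the background limit of the dimmer arrays, taken as the higher of the dimmest detected signal and the probe's own signal. The log2 values of such genes are fitted differences from background-level signal, and undetected members move some list medians, which are then also given with those genes at their bound.

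The targeted genes were examined first. Rela, which encodes RelA, was detected on all arrays but dimmer wherever the genotype lacks it: normalized log2 intensity was 8.46 to 9.16 in crel-/-p65-/-, 7.01 to 8.36 in crel-/-p65-/-relb-/- and 8.87 to 9.01 in crel-/-p65-/-irf3-/-, against 9.83 to 11.97 in WT and 11.54 to 12.23 in ifnar-/-. In unstimulated cells the difference from WT was −2.41 ± 0.34 (SE) in crel-/-p65-/-relb-/- (adjusted p = 0.031). It was −1.62 ± 0.34 in crel-/-p65-/- (adjusted p = 0.987) and −1.44 ± 0.44 in crel-/-p65-/-irf3-/- (adjusted p = 0.88), both short of the threshold. The call in crel-/-p65-/-relb-/- was lost when any of several single arrays was left out (the WT array of the LPS, TNF or IFNb course, or any of the 4 knockout arrays), with values from −2.87 to −1.95. Relb was detected on 0 of 4 arrays of crel-/-p65-/-relb-/-, with intensities of 4.55 to 5.08. It was also detected on 0 of 4 arrays of crel-/-p65-/-irf3-/-, on 0 of 3 of the crel-/-p65-/- PDGFb course and on 2 of 6 of the WT IFNb course, so this does not check the deletion of RelB. Irf3 had 3 probes, each detected on all 40 arrays, and in crel-/-p65-/-irf3-/- the brightest, which represents the gene, lay within the range of WT arrays (10.13 to 10.44, against 9.41 to 10.82), so they do not check that deletion. Whether they lie outside the deleted part is not given in the sources used here. Rel, which encodes c-Rel, was detected on 1 array and Ifnar1 on 0, so neither checks its genotype. The labels of the irf3-/- and ifnar-/- arrays were taken as given.

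To establish the wild-type response to the pathogen signal, WT cells were followed through 8 h of LPS. LPS is recognised by TLR4 at the cell surface, and adaptor proteins carry the signal to NF-κB, to MAP kinases and to IRF3. NF-κB drives genes of inflammation such as the neutrophil attractants Cxcl1 and Cxcl2 and the cytokines Il1b and Tnf. IRF3 helps to start interferon production, and secreted interferon then switches on antiviral genes through its own receptor. In 225 genes the F-test over the 3 times passed, 213 with higher and 12 with lower expression (731 genes at an unadjusted p under 0.05). The largest change of the induced genes fell at 1 h in 8, at 3 h in 29 and at 8 h in 176. At 1 h the highest were the cytokine genes Cxcl2 (6.90 ± 0.42 on the log2 scale, at least 57.4-fold, adjusted p = 2.37e-05) and Tnf (6.33 ± 0.28, at least 31.3-fold, adjusted p = 5.78e-06). The chemokines Ccl4 and Ccl3 followed with 5.22 and 5.01. Il1b, which encodes a fever-inducing cytokine, reached 8.90 ± 0.29 at 8 h (at least 196-fold, adjusted p = 5.78e-06). Cxcl9, a T cell attractant, was not detected at 1 h and reached 9.46 ± 0.36 at 8 h (at least 412-fold, adjusted p = 1.01e-05). Ccl5, another T cell attractant, reached 8.95 and Cxcl10 8.53 at 8 h, both from unstimulated levels partly at background, and the antiviral gene Rsad2 was 154-fold higher at 3 h. The transcript of interferon beta itself, Ifnb1, was seen early: at least 4.62-fold at 1 h and 3.25-fold at 3 h, with a log2 change of 1.12 at 8 h.

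NF-κB targets were higher with LPS in WT cells. Of 42 measured, 29 were called higher with LPS (40 when adjusted over the list alone), and the list median was 0.79, 3.19 and 3.66 at 1, 3 and 8 h (0.70, 2.87 and 3.62 with undetected genes at their bound; adjusted p = 0.00221 at 8 h). The adjusted p of this and every other list test is the one with an estimated correlation between genes; of 429 list tests, 174 passed with camera's preset correlation and 83 with the estimated one. Tnfaip3, whose product A20 dampens the pathway, was higher by 6.54 at 3 h, and the acute-phase gene Saa3 at least 146-fold higher at 8 h. The median of interferon-stimulated genes was 2.21 at 3 h and 4.0 at 8 h (2.14 and 3.68 with bounds; adjusted p = 0.0065 at 8 h), with 36 of 46 called higher (39 adjusted over the list alone). Ifi205, a DNA sensor family member, was at least 55.1-fold higher at 8 h, the GTPase gene Tgtp1 at least 24-fold, and Cmpk2, a nucleotide kinase next to Rsad2 in the antiviral programme, reached 6.49. All 9 early genes associated with IRF3 were called (9 adjusted over the list alone), with medians of 1.91, 5.79 and 5.46. Immediate-early and growth-factor genes peaked at 1 h with a median of 1.03 (adjusted p = 0.00918). Of these 40 genes, 6 were called higher (11 higher and 2 lower adjusted over the list alone), among them the transcription factors Atf3 (3.32), Egr4 (3.09) and Fosb (2.34) and the survival gene Ier3 (2.70). Genes of MHC class I presentation, which load peptides for T cells, had medians of 1.44 and 3.07 at 3 and 8 h (0.99 and 3.07 with bounds). Of 16, 6 were called (8 adjusted over the list alone), led by the immunoproteasome subunit Psmb9 (5.21 ± 0.52 at 8 h, adjusted p = 0.00217), while the class I heavy chain H2-K1 stood at 4.57 without passing (adjusted p = 0.2). Short-lived transcripts with AU-rich elements had medians of 1.83, 3.27 and 3.19, with 14 of 25 called (19 adjusted over the list alone).

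Genes of cholesterol synthesis passed camera at 8 h of LPS, and the call was lost with an estimated correlation (adjusted p = 0.0914). Their median was −1.57 (−1.51 with bounds), 13 of 19 were at least 2-fold lower, and 2 were called (5 adjusted over the list alone). The mevalonate enzyme Mvd was at least 4.43-fold lower (adjusted p = 0.0377), whereas Sqle (−3.51, adjusted p = 0.2), Insig1 (−2.64, adjusted p = 0.141) and Hmgcs1 (−2.35, adjusted p = 0.102) did not pass. The lowest called genes at 3 and 8 h included the transcription regulators Tox (−3.56 at 3 h, adjusted p = 0.0249) and Osr1 (−3.10 at 8 h, adjusted p = 0.0164), the glycogen gene Ppp1r3c (−3.70 at 3 h) and the clock gene Dbp (−3.06 at 8 h). Tgoln1 was lower on the 1 h array alone (−4.75). With the unstimulated array of the LPS course as baseline 142 genes passed, and with course as a block 95. The fit with an additive spread, chosen after seeing the data, called 2, but its spread takes in differences between genotypes. Tox, Osr1, Ppp1r3c and Dbp were among those not called against the same course's baseline. The median level of leukocyte markers was 8.58 to 9.17 on the arrays of this course, against 6.36, 6.74 and 6.86 on the other unstimulated WT arrays, and 20 of the 225 genes correlated with them over unstimulated arrays (r above 0.7).

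**Figure D1:**
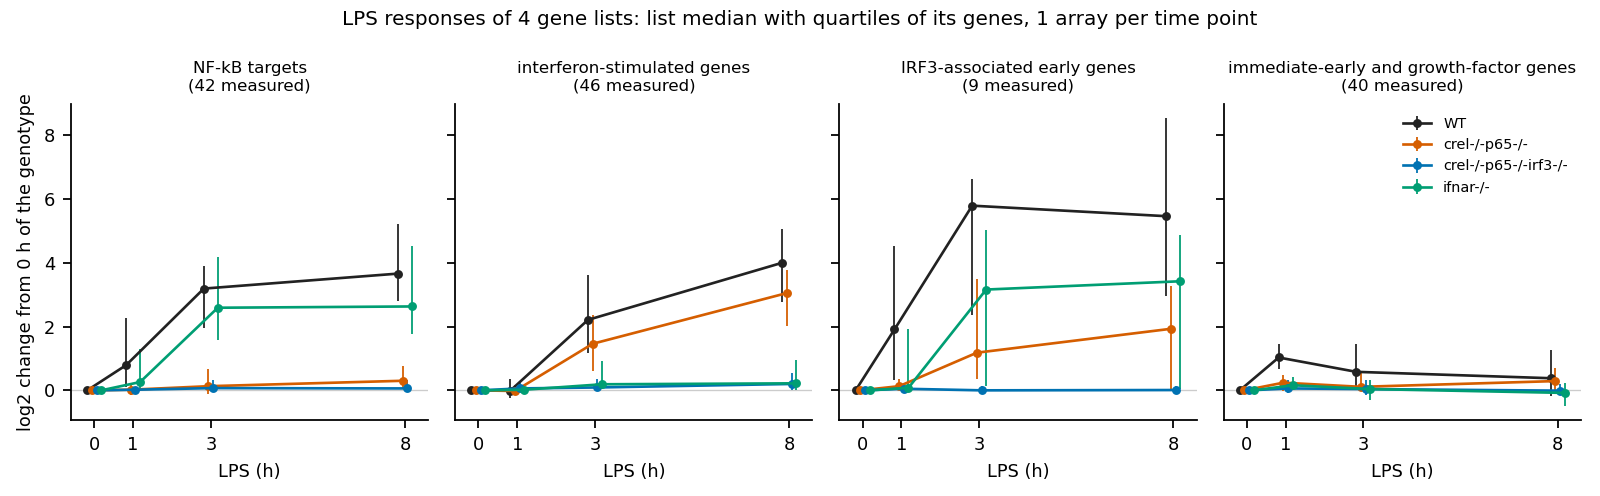
Median log2 change from the unstimulated arrays of the same genotype (y axis) against hours of LPS (x axis) in 4 genotypes, for NF-κB targets (42 genes), interferon-stimulated genes (46), early genes associated with IRF3 (9) and immediate-early genes (40); points are list medians and bars the quartiles of the genes. At 8 h the NF-κB targets stand at 3.66 in WT and 0.30 in crel-/-p65-/-, and the interferon-stimulated genes at 4.0 in WT and 0.22 in ifnar-/-.

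TNF activates NF-κB and MAP kinases but gives little direct input to IRF3, so its course shows which LPS-responsive genes an NF-κB stimulus reaches by itself. The inhibitors Tnfaip3 and Nfkbie, which encodes IκBε, belong to the feedback that ends each pulse of NF-κB. Sele encodes E-selectin and Icam1 an adhesion molecule, both of which help leukocytes to leave the blood. In WT cells 50 genes passed, 48 higher and 2 lower (334 at an unadjusted p under 0.05), with 9, 19 and 20 of the induced genes peaking at 1, 3 and 8 h. At 1 h the highest were Tnfaip3 (5.21 ± 0.43, adjusted p = 0.00114), Cxcl1 (5.01 ± 0.61, adjusted p = 0.00993), the transcription factor Irf1 (4.01 ± 0.30, at least 7.33-fold) and Sele (4.0 ± 0.28, at least 7.24-fold). Nfkbie was at least 24.6-fold higher at 3 h, when Icam1 stood at 4.59. At 8 h the highest were Ccl5 (7.72 ± 0.46, adjusted p = 0.000458), Saa3 (at least 68.5-fold), Cxcl9 (at least 34.9-fold) and the secreted lectin Chil1 (at least 14.8-fold). NF-κB targets had medians of 0.82, 1.37 and 1.58 (0.32 and 1.23 with bounds at 1 and 8 h; adjusted p = 0.0065 at 8 h), and 11 of 42 were called (29 adjusted over the list alone). Ccl2, a monocyte attractant, reached 5.44 without passing (adjusted p = 0.0502). Interferon-stimulated genes rose late as a group, with a median of 1.04 at 8 h (0.98 with bounds, adjusted p = 0.0312), although 2 were called (14 adjusted over the list alone), the GTPase gene Gbp3 (3.80) and Parp14 (3.57) among the highest. MHC class I genes had medians of 0.90 and 1.72 at 3 and 8 h, with Psmb10 (3.21) and Psmb8 (2.95) called. Immediate-early genes had a median of 0.68 at 1 h (0.50 with bounds), and Atf3 (3.26), Egr4 (3.13) and Ier3 (3.02) were called. Relb, itself an NF-κB target, was higher at 3 h by 3.08 ± 0.37 (adjusted p = 0.0101). The lower calls were Fam180a (−2.16) and Pop4, the latter on the 8 h array alone (−5.02).

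The TNF count rested on few arrays. It was 18 with the baseline of the same course, 0 with course as a block, 95 with the additive spread and 31 with 75th percentile scaling; leaving out the unstimulated WT array of the TNF course raised it to 146, while it was 33 without the WT array of the PDGFb course, 32 without either crel-/-p65-/- array and 33 without either crel-/-p65-/-relb-/- array.

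PDGFb signals through a receptor tyrosine kinase and MAP kinases. It was taken as a stimulus with little input to NF-κB or IRF3, which was not tested. Its transcripts are mostly immediate-early genes, which are switched on within minutes from factors already present. Egr4 encodes a zinc finger transcription factor, Fosb a member of the AP-1 complex, and Atf3 a stress-induced factor that can repress inflammatory genes. These 3 were the genes called (88 at an unadjusted p under 0.05), all at 1 h. Egr4 was at least 16.5-fold higher (5.30 ± 0.31, adjusted p = 0.00394), Fosb at least 12.9-fold (4.57 ± 0.29, adjusted p = 0.00397) and Atf3 at least 6.59-fold (3.80 ± 0.31, adjusted p = 0.0206). By 3 h they stood at 0.09, 0.63 and 0.30. Immediate-early genes as a list had a median of 1.19 at 1 h (adjusted p = 0.0065), 25 of 40 were at least 2-fold up and 11 were called when adjusted over the list alone. Others in the list were high without passing, such as Egr2 (3.81, adjusted p = 1), Ptgs2 (3.52, adjusted p = 1) and Fos (2.79, adjusted p = 1). Transcripts with AU-rich elements had a median of 1.10 at 1 h (adjusted p = 0.0138), with 1 called (6 adjusted over the list alone) and Il6 at 3.09 (adjusted p = 0.673). No NF-κB target was called (1 adjusted over the list alone). The count of 3 held with the baseline of the same course, was 9 with the additive spread, 1 with 75th percentile scaling and 0 with probes detected on at least 10 arrays or with course as a block.

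IFNb acts through its receptor IFNAR, and its course gave the reference for the interferon branch. Rsad2 encodes the antiviral enzyme viperin, Mx1 and Mx2 encode GTPases that trap viral particles, and Oasl1 and Ifit2 belong to the families that sense or block foreign RNA. Cd274 encodes PD-L1, which restrains T cells. In WT cells 129 genes passed, 126 higher and 3 lower (716 at an unadjusted p under 0.05), peaking at 1, 3 and 8 h in 6, 50 and 70 of the induced genes. Already at 1 h Rsad2 stood at 6.32, Cxcl10 at 5.95, Cd274 at 5.57 and Mx2 at 4.50. At 3 h Rsad2 reached 7.69 ± 0.55 (207-fold, adjusted p = 0.000205) and Oasl1 7.20 ± 0.30 (at least 60.7-fold, adjusted p = 4.54e-05), and at 8 h Mx1 was at least 27-fold and Ifit2 6.00 higher. Interferon-stimulated genes had medians of 1.32, 3.54 and 4.07 (3.84 with bounds at 8 h, adjusted p = 0.0065), with 35 of 46 called (41 adjusted over the list alone). MHC class I genes reached 2.31 and 2.76 at 3 and 8 h, and 6 of 16 were called (11 adjusted over the list alone), among them Psmb9 (5.38), the transactivator Nlrc5 (4.65), Psmb8 (4.56) and the peptide transporter Tap1 (3.72). Irf1 was at least 6.52-fold higher at 1 h. Of NF-κB targets 1 was called (3 adjusted over the list alone), and of the early genes associated with IRF3, 3 (5 adjusted over the list alone). Zfp36, which encodes an mRNA decay factor, rose by 2.77 and the kinase gene Map3k8 by 3.67. Genes of the ATF4 stress response had 1 lower call, Chac1 (−2.11 at 3 h, adjusted p = 0.0358), and 4 lower when adjusted over the list alone. The count was 59 with the baseline of the same course, 40 with course as a block and 2304 with the additive spread. It was 214 without the unstimulated WT array of the IFNb course, 80 without that of the LPS course, 75 without either crel-/-p65-/- array and 77 without either crel-/-p65-/-relb-/- array.

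To see which branch could account for each LPS-responsive gene, the 213 genes induced by LPS were set against the other agents. Of these, 37 were also called higher with TNF, 93 with IFNb and 3 with PDGFb. Independent lists would share 1.11, 2.92 and 0.07 genes, and 100 simulations of unchanged groups against the same unstimulated arrays gave a mean of 0, 0 and 0.01 (highest 0, 0 and 1). Neither figure covers both shared controls and real effects, and the simulated arrays had no shift shared within a course. No gene was called in opposite directions. Across all 9180 genes, which are not independent replicates, the mean change over the 3 times correlated between LPS and TNF, PDGFb or IFNb at −0.02, 0.29 and 0.18 (Spearman's rho −0.12, 0.32 and −0.06), where shared unstimulated arrays alone gave 0.43 in simulation. The covariances were −0.007, 0.103 and 0.082, against a simulated 0.056. With the unstimulated WT arrays split, the correlations ran from −0.51 to 0.37, from −0.13 to 0.35 and from −0.37 to 0.44, and with each course's own baseline they were 0.64, 0.17 and 0.51. Of the 29 NF-κB targets induced by LPS, 11 were called with TNF and not IFNb and 17 with neither, and of the 36 interferon-stimulated genes 32 were called with IFNb and not TNF. In all, 26 LPS-induced genes were called with TNF and not IFNb, 11 with both, 82 with IFNb and not TNF and 94 with neither. A missing call is no evidence of no response: Ccl2, called with neither, stood at 5.44 with TNF and 3.94 with IFNb. The median level of leukocyte markers was 9.17 on the unstimulated array of the LPS course, against 6.36, 6.74 and 6.86 in the other WT courses, so these classes are not separated from differences in cell mixture. The total of LPS-responsive genes shared with any other agent was 120. It was 61 with own baselines, 36 with course as a block, 0 with the additive spread and 75 without either crel-/-p65-/- array.

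To test which LPS responses need NF-κB, the LPS course of crel-/-p65-/- cells was compared with that of WT cells by an interaction test. RelA and c-Rel carry most of the activating function of NF-κB at inflammatory promoters. In 34 genes the response differed, all of them weaker in the knockout (203 at an unadjusted p under 0.05). Il1b differed by −8.94 ± 0.43 at 8 h (adjusted p = 0.00032), Cxcl2 by −7.60 ± 0.62 (adjusted p = 0.00165), Saa3 by −7.50 ± 0.52 (adjusted p = 0.00165), Tnf by −7.06 ± 0.41 (adjusted p = 0.000518) and Ccl5 by −7.02 ± 0.68 (adjusted p = 0.00685). Il1b, Tnf, Cxcl2 and Saa3 were not detected on the knockout's 8 h array. Tnfaip3 differed by −6.13, Nos2, which encodes inducible nitric oxide synthase, by −4.38, and Ifnb1 by −3.28 (adjusted p = 0.0472). NF-κB targets differed by medians of −0.81, −2.43 and −2.87 (adjusted p = 0.00221 at 8 h), with 10 of 42 called (31 adjusted over the list alone). In the knockout their median response at 8 h was 0.30 (0.21 with bounds), and 9 of 42 were at least 2-fold up, against 40 in WT. Transcripts with AU-rich elements differed by −1.74, −1.63 and −1.61, with 3 of 25 called (11 adjusted over the list alone). Immediate-early genes differed by −0.71 at 1 h (adjusted p = 0.0176), with none called over all genes and 4 adjusted over the list alone.

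Interferon-stimulated genes still responded to LPS without c-Rel and RelA. Their median response was 1.46 and 3.05 at 3 and 8 h in crel-/-p65-/- cells (2.59 with bounds at 8 h), 42 of 46 were at least 2-fold up at 8 h as in WT, and 1 was called as weaker (3 adjusted over the list alone). The list differed by −0.75 at 8 h (adjusted p = 0.0457) and by −0.61 at 3 h, where the call was lost with an estimated correlation (adjusted p = 0.066). Cxcl10 stood at 6.74 at 8 h, Rsad2 stood at 6.69 at 3 h, Ifit2 at 4.95 and Mx1 at least 6.06-fold at 8 h; the differences from WT did not pass for Rsad2 (adjusted p = 1) or Cxcl10 (adjusted p = 0.942). Cxcl9 was at least 29.6-fold higher at 8 h, a response weaker than in WT by −3.61 ± 0.54 (adjusted p = 0.0216), and Tgtp1 was weaker by −2.57 (adjusted p = 0.0404). The early genes associated with IRF3 had medians of 1.18 and 1.93 at 3 and 8 h (0.97 with bounds at 8 h), a difference of −3.42 at 8 h (adjusted p = 0.0117) and 4 of 9 called (8 adjusted over the list alone). MHC class I genes differed by −0.75 at 8 h (adjusted p = 0.0449) with none called in either count. Macrophage and leukocyte markers were dimmer in this course too: their median level on the unstimulated array was 9.17 in the WT LPS course and 5.92 in the crel-/-p65-/- LPS course. Of the 34 genes, 4 correlated with those markers over unstimulated arrays (r above 0.7) and 30 did not, where 183 of all 9180 genes did. Genes near background on those arrays, such as Il1b, Il1a and Tnf, have little signal to correlate. A lack of correlation therefore does not separate a gene from leukocytes. The count was 21 with the baseline of the same course, 6 with course as a block, 0 with the additive spread, 8 with 75th percentile scaling, 19 with the actinomycin D 0 h array joined with WT LPS 3 h, and 80 with no filter on dim probes; it was 11 or 13 without one of the knockout's own unstimulated arrays and 19 without either crel-/-p65-/-relb-/- array.

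Deleting IRF3 as well asked what remained of the LPS response once both branches were removed. IRF3 acts at the promoters of Ifnb1, Ccl5 and Cxcl10 and so lies upstream of secreted interferon. In crel-/-p65-/-irf3-/- cells 55 genes responded differently from WT, again all more weakly (298 at an unadjusted p under 0.05), and they included all 34 of crel-/-p65-/- cells. All 55 were induced by LPS in WT. Both comparisons use the same WT LPS arrays and unstimulated WT arrays, so the shared genes and direction are not independent evidence. The largest differences at 8 h were in Cxcl9 (−9.60 ± 0.59, adjusted p = 0.000559), Il1b and Ccl5 (both −8.94), Cxcl2 (−8.35), Cxcl10 (−7.90 ± 1.09, adjusted p = 0.0418) and Ccl3 (−7.64). Interferon-stimulated genes now differed by −2.15 and −3.77 at 3 and 8 h (adjusted p = 0.0065), with 10 of 46 called (37 adjusted over the list alone), including Ifi205 (−6.34), Tgtp1 (−5.85), Oasl1 (−5.72), Cmpk2 (−5.59), Mx1 (−5.42) and Ifit2 (−5.38). Their median response was 0.09 and 0.20, with 3 of 46 at least 2-fold up. NF-κB targets differed by −2.92 and −3.43 (12 called, 27 adjusted over the list alone), the early genes associated with IRF3 by −5.47 and −5.33 (6 of 9 called, 9 adjusted over the list alone), and MHC class I genes by −2.94 at 8 h (none called, 6 adjusted over the list alone). Transcripts with AU-rich elements differed by −2.95 at 3 h (7 called, 13 adjusted over the list alone), among them Il6 (−5.92, adjusted p = 0.00922). A few genes were still higher with LPS in the array values, such as Cxcl1 (3.03 ± 0.78 at 3 h) and the NF-κB regulator Nfkbiz (2.43), which were named from the lists. These values set 1 array against 1, and no test of the response within this genotype was run. The median level of leukocyte markers was at background here (4.59 on the unstimulated array, where 1 of 12, Lyz2, was detected). Of the 55 genes, 6 correlated with those markers and 49 did not, with the same limit for genes near background on unstimulated arrays. The count was 31 with 75th percentile scaling, 24 with probes detected on at least 10 arrays, 18 with the actinomycin D 0 h array joined with WT LPS 3 h, and 0 with course as a block or with the additive spread; it was 35 without the WT array of the PDGFb course, 28 without either crel-/-p65-/- array and 29 without either crel-/-p65-/-relb-/- array.

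The step from crel-/-p65-/- to crel-/-p65-/-irf3-/- cells was tested directly, a comparison added after seeing the data. It called 0 genes in limma (63 at an unadjusted p under 0.05), the highest-ranked being Cxcl9 (−5.99) and Mx1 (−3.75), each with an adjusted p of 0.169. As a group, interferon-stimulated genes differed by −1.30 and −2.75 at 3 and 8 h (adjusted p = 0.00326 and 0.00259 with an estimated correlation), and MHC class I genes by −1.66 at 8 h (adjusted p = 0.00326). Early genes associated with IRF3 differed by −1.26 at 3 h (adjusted p = 0.0178) and by −1.92 at 8 h, lost with an estimated correlation (adjusted p = 0.0548). The AU-rich transcripts differed by −0.62 at 3 h (adjusted p = 0.0362) and by −0.75 at 8 h, also lost (adjusted p = 0.0641). NF-κB targets, at −0.06 and −0.13, passed camera's preset correlation at both times (adjusted p = 0.00834 and 0.00187) and were lost with an estimated one (adjusted p = 0.263 and 0.202). Immediate-early genes, at −0.17 and −0.22, behaved likewise (adjusted p = 0.0333 and 6.72e-05, then 0.598 and 0.202). So did leukocyte markers at 1 h (−0.52, adjusted p = 0.0212, then 0.931) and epithelial markers at 3 h (0.98, adjusted p = 0.000169, then 0.246).

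Cells lacking IFNAR cannot hear the interferon they secrete, so their LPS course asked which genes are reached directly and which in a later step. Mx1 and Oasl1 depend on interferon signalling, whereas Cxcl10 and Ifnb1 can be switched on by IRF3 and NF-κB alone. In ifnar-/- cells 12 genes responded more weakly than in WT (164 at an unadjusted p under 0.05). All were among the 55 above, which were found against the same WT arrays. The 12 genes therefore give no independent support. They included Cmpk2 (−6.31 ± 0.73 at 8 h, adjusted p = 0.0257), Cxcl9 (−6.04 ± 0.59, adjusted p = 0.0177), Tgtp1 (−5.81 ± 0.46, adjusted p = 0.00881), Oasl1 (−5.55 ± 0.49, adjusted p = 0.00881), Mx1 (−5.32, adjusted p = 0.00881), the hyaluronan synthase Has1 (−4.65 at 3 h) and Nos2 (−4.21). Rsad2 (−7.13, adjusted p = 0.0613) and Ifit2 (−5.58, adjusted p = 0.0575) fell short. Interferon-stimulated genes differed by −1.53 and −3.16 (adjusted p = 0.00694 and 0.0065), with 4 of 46 called (29 adjusted over the list alone), and their median response was 0.22 at 8 h, with 10 of 46 at least 2-fold up. MHC class I genes differed by −1.51 at 8 h (adjusted p = 0.00988; none called, 3 adjusted over the list alone). NF-κB targets responded without the interferon receptor. Their median was 2.63 at 8 h, 40 of 42 were at least 2-fold up, and the difference from WT was −0.27 at 3 h (adjusted p = 0.108 with an estimated correlation) and −0.92 at 8 h (adjusted p = 0.0203), with none called (1 adjusted over the list alone). Saa3 was 364-fold higher at 8 h, Il1b at least 123-fold, Cxcl2 at least 105-fold and Ccl5 at least 96.6-fold. Early genes associated with IRF3 had medians of 3.16 and 3.42, with 2 of 9 called as weaker (5 adjusted over the list alone), and Cxcl10 was at least 24-fold higher at 3 h. Transcripts with AU-rich elements differed by −1.24, −1.07 and −1.56 (1 adjusted over the list alone) and immediate-early genes by −0.85 at 1 h (3 adjusted over the list alone), with no call over all genes. Ifnb1 was not detected with LPS in ifnar-/- cells, with a log2 change of 0.08 at 1 h against 3.42 in WT. These arrays therefore do not separate the loss of the receptor from a lack of Ifnb1 induction. Ifnb1 stood at 0.14 at 1 h in crel-/-p65-/- cells too, where interferon-stimulated genes still responded.

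The count of 12 depended on several settings and arrays. It was 0 with 75th percentile scaling, with course as a block, with the additive spread, with the actinomycin D 0 h array joined with WT LPS 3 h and without any one of the 4 crel-/-p65-/- or crel-/-p65-/-relb-/- arrays, 5 without the WT array of the LPS or the PDGFb course, and 61 with no filter on dim probes. Leukocyte markers were dimmer here than in the WT LPS course as well, with median levels of 7.49 and 9.17 on the unstimulated arrays.

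Classing the 213 LPS-induced genes by the agents with which they were also called, each taken at its WT peak time, set the knockouts side by side. The genes were selected on the WT arrays, which favours larger values in WT. Of the 26 genes called with TNF and not IFNb, 5 (19.2%) were at least 2-fold up with LPS in crel-/-p65-/- cells and 24 (92.3%) in ifnar-/- cells. Of the 82 called with IFNb and not TNF, 68 (82.9%) were up in crel-/-p65-/- and 21 (25.6%) in ifnar-/-. Of the 11 called with TNF and IFNb, 9 (81.8%) and 8 (72.7%) were up. Of the 94 called with neither, some of which had large changes with these agents, 19 (20.2%) and 57 (60.6%) were up. In crel-/-p65-/-irf3-/- cells 7 of all 213 (3.3%) reached 2-fold, and the median log2 change over the 213 was 3.47 in WT, 0.92 in crel-/-p65-/-, 0.06 in crel-/-p65-/-irf3-/- and 1.11 in ifnar-/-. Leukocyte markers had the same order on the unstimulated arrays of these courses, with median levels of 9.17, 5.92, 4.59 and 7.49. Genes called with IFNb and not TNF did not follow that order. The shares are therefore not separated from differences in cell mixture.

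**Figure D2:**
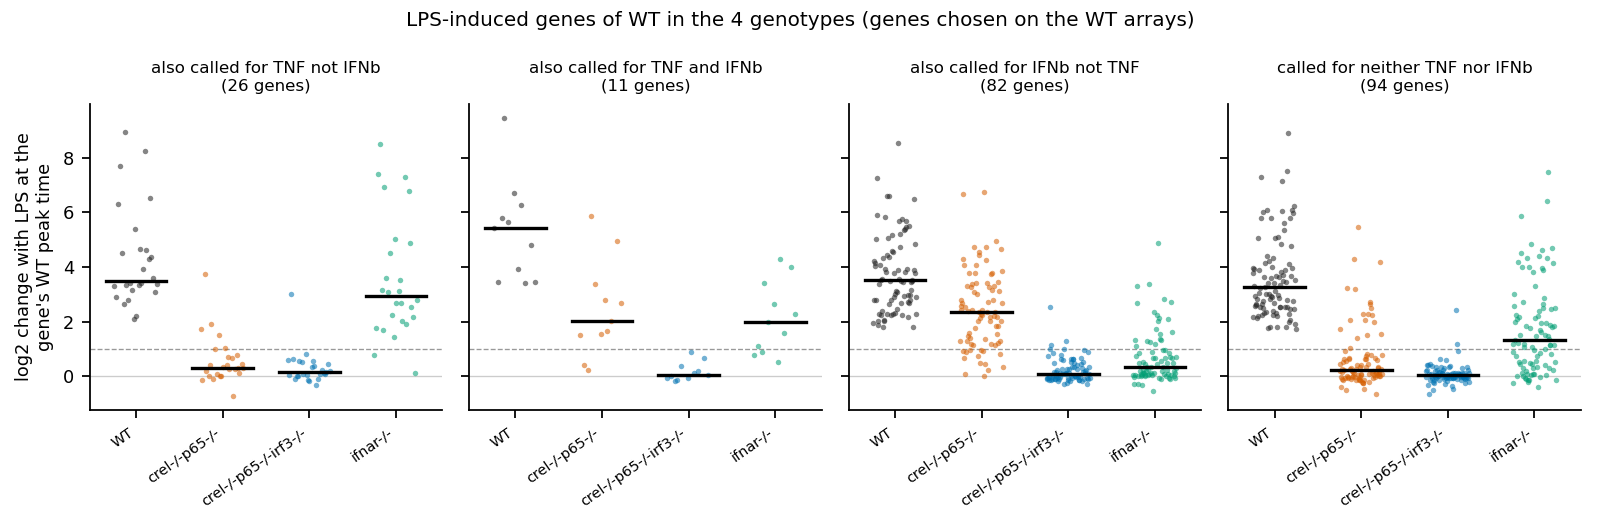
Log2 change with LPS at the time of the WT peak (y axis) of the 213 genes induced by LPS in WT, one point per gene, in 4 genotypes (x axis), in panels by whether the gene was also called with TNF or IFNb; bars are medians and the dashed line marks 2-fold. Genes called with TNF and not IFNb have medians of 3.50 in WT, 0.32 in crel-/-p65-/- and 2.94 in ifnar-/-, and genes called with IFNb and not TNF 3.51, 2.36 and 0.33.

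The remaining knockout courses asked whether single agents still work without NF-κB. The immediate-early genes of PDGFb are driven by serum response factor and AP-1, TNF acts mainly through NF-κB, and IFNb acts through IFNAR. The PDGFb response of crel-/-p65-/- cells differed from WT in 0 genes in limma (5 at an unadjusted p under 0.05). Those 5 lie far below a share of 0.05 of the 9180 genes, and 0 calls do not show an unchanged response. At 1 h Egr4 was at least 17.8-fold, Atf3 at least 7.48-fold and Fosb at least 4.86-fold higher, and the immediate-early median was 1.38 (26 of 40 at least 2-fold up). Interferon-stimulated genes differed by 0.38 at 8 h by camera, lost with an estimated correlation (adjusted p = 0.213). With TNF at 1 h in crel-/-p65-/-relb-/- cells, 0 genes differed in limma (76 at an unadjusted p under 0.05), with Irf1 nearest (−4.08 ± 0.45, adjusted p = 0.0509). As a list, NF-κB targets differed by −1.01 (adjusted p = 0.0112; 7 adjusted over the list alone): their median response was 0.00 in the knockout, with 2 of 42 at least 2-fold up, against 0.82 and 20 of 42 in WT. Leukocyte markers differed as well, with a median level of 4.55 and 0 of 12 detected on the knockout's unstimulated array of this course, against 6.74 in the WT TNF course. Tnfaip3 stood at 1.28 and Cxcl1 at 0.13 in the knockout, although the differences of −3.94 and −4.88 did not pass (adjusted p = 0.394 and 0.596). The immediate-early median was 0.85, and Fosb was at least 7.82-fold and Egr4 at least 4.05-fold higher. Transcripts with AU-rich elements differed by −1.06, lost with an estimated correlation (adjusted p = 0.0542; 6 lower and 1 higher adjusted over the list alone). With IFNb at 8 h in crel-/-p65-/-relb-/- cells, 0 genes differed in limma (130 at an unadjusted p under 0.05). Interferon-stimulated genes had a median of 4.31, with 43 of 46 at least 2-fold up against 42 in WT. The difference of 0.61 was lost with an estimated correlation (adjusted p = 0.107; 1 higher adjusted over the list alone). Rsad2 was at least 255-fold, Cxcl10 at least 218-fold and Mx1 at least 19-fold higher, and MHC class I genes had a median of 2.83. Trend and robust variances gave 3 calls for TNF and 2 for IFNb, and no filter on dim probes gave 5 and 4.

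Next, IFNb given 2 h before TNF was compared with TNF alone, which asks how the branches behave when both are active. The genes at issue are those with sites for NF-κB and for interferon-activated factors, such as Cxcl9 and Cxcl10. Of 71 genes that differed, 58 were higher with both agents and 13 lower (1065 at an unadjusted p under 0.05). Interferon-stimulated genes had list differences of 1.13 and 2.49 at 3 and 8 h (adjusted p = 0.0274 and 0.00988) and 15 of 46 called (36 adjusted over the list alone). At 8 h Ifi205 was at least 30.8-fold, Xdh, which encodes xanthine oxidoreductase, at least 31.7-fold, the chemokine receptor-like gene Ccrl2 at least 47-fold and the hormone gene Sct at least 28.4-fold higher than with TNF alone, and Rsad2 51.1-fold. All these differences passed, with Oasl1 (5.5 ± 0.38) and Tgtp1 (5.24 ± 0.36) at an adjusted p of 0.000974. Cxcl9 was 3.68 and Cxcl10 4.43 ± 0.86 higher (adjusted p = 0.00565 and 0.0437), Il6 2.49 and Il15, a growth factor for natural killer cells, 4.13. Of the early genes associated with IRF3, 5 of 9 were called (5 adjusted over the list alone), although the list call was lost with an estimated correlation (adjusted p = 0.0914). MHC class I genes differed by 1.2 at 8 h (adjusted p = 0.033; 1 called, 6 adjusted over the list alone), and genes of the ATF4 response by −0.81 at 3 h (adjusted p = 0.0416; 1 lower adjusted over the list alone). Saa3 (−3.69 ± 0.44, adjusted p = 0.0073) and Chil1 (−3.46 ± 0.44, adjusted p = 0.0136) were lower with both agents, as were Fam167a (−4.29) and Lysmd1 (−2.72 at 3 h). NF-κB targets had 1 call higher and 1 lower (7 and 1 adjusted over the list alone).

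The arrays of this comparison come from different courses, and with each course's own baseline only 5 genes passed, among them Sct (adjusted p = 0.0322), Oasl1 (adjusted p = 0.0322) and Tgtp1 (adjusted p = 0.034); Saa3 and Chil1 did not (adjusted p = 0.297 and 0.387). On those baselines the 8 h medians with TNF, IFNb and both were 1.96, 0.06 and 2.17 for NF-κB targets, 0.86, 4.29 and 4.08 for interferon-stimulated genes, and 0.63, 1.64 and 3.12 for early genes associated with IRF3. At 3 h they were 0.34, 3.94 and 1.88 for interferon-stimulated genes. Exposure to IFNb is not matched between these arrays. A rise over TNF alone also does not separate an effect of IFNb by itself from one of both agents. The 48 TNF-induced genes had medians of 2.68 with TNF and 2.92 with both, with 16 at least 2-fold above and 13 at least 2-fold below TNF alone. The share of higher calls was 81.7% and became 97.1% with 75th percentile scaling (33 of 34 genes). The count was 0 with course as a block, 303 with the additive spread, 137 with no filter on dim probes, 40, 46, 123 and 132 without the unstimulated WT array of the LPS, PDGFb, TNF and IFNb course, and 28 without any one of the crel-/-p65-/- or crel-/-p65-/-relb-/- arrays.

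Actinomycin D blocks transcription, so the fall of a transcript after its addition reflects how quickly it decays. Many LPS-induced messages carry AU-rich elements in their 3′ ends, which mark them for decay. Added after 3 h of LPS in WT cells, it gave 1 call in limma (228 at an unadjusted p under 0.05), Chac1, which encodes a glutathione-degrading enzyme and was at least 38.2-fold lower at 3 h (−5.90 ± 0.42, adjusted p = 0.00792). The lists decided more than single genes. Short-lived transcripts with AU-rich elements had medians of −0.79 and −1.62 at 1 and 3 h (adjusted p = 0.00821 and 0.00988; 12 of 25 adjusted over the list alone), and immediate-early genes −0.50 and −1.34 (adjusted p = 0.0137 and 0.00988; 12 of 40 adjusted over the list alone). The members of the AU-rich list were chosen as short-lived, so its fall does not test whether AU-rich elements speed decay. NF-κB targets had −0.15 and −0.32 (adjusted p = 0.0329 and 0.0442; 7 adjusted over the list alone). Nfkbia (−5.06 ± 0.80, adjusted p = 0.217), Tnfaip3 (−4.80 ± 0.55, adjusted p = 0.153), the phosphatase genes Dusp1 (−4.74, adjusted p = 0.412) and Dusp6 (−4.43, adjusted p = 0.348), Egr1 (−3.89, adjusted p = 0.153) and Csf2 (−2.82, adjusted p = 0.153) had low values at 3 h without passing. By contrast Cxcl10 stood at −0.06, Ccl5 at 0.00, Ifit2 at −0.01, Rsad2 at −0.10, Cxcl1 at −0.47 and Cxcl2 at −0.50. Among genes detected before the drug, the 3 h median was 0.08 for all 8447, 0.09 for the 176 induced by LPS, −1.72 for 24 AU-rich, −1.62 for 33 immediate-early, −0.32 for 42 NF-κB and 0.29 for 41 interferon-stimulated genes. The array before the drug showed a smaller interferon response than the WT LPS 3 h array, with an interferon-stimulated median of 0.53 against 2.21 above unstimulated WT cells (2.62 against 3.19 for NF-κB targets), which limits what these values say of interferon-stimulated transcripts. Arrays are scaled to a common distribution, so these values are relative to the other transcripts and are no half-lives. The count was 10 with the 0 h array joined with WT LPS 3 h, 450 with the additive spread, 0 with the authors' values or with course as a block, and 0 without any one of the crel-/-p65-/- or crel-/-p65-/-relb-/- arrays.

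**Figure D3:**
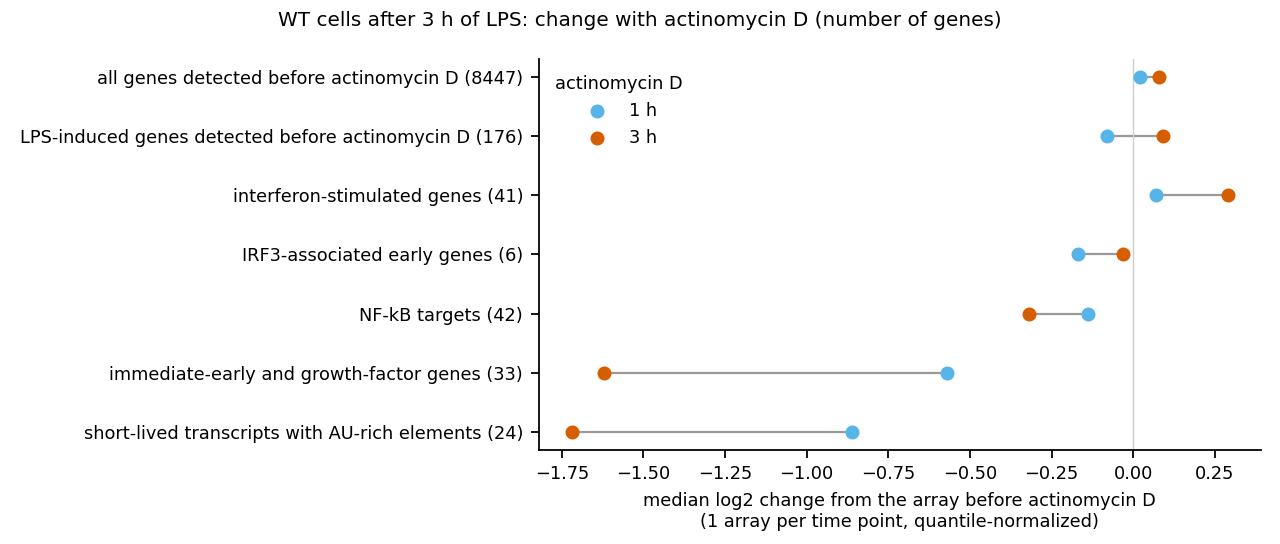
Median log2 change (x axis) 1 h and 3 h after actinomycin D for each set of genes detected before the drug (y axis, with the number of genes), with 1 array per time. At 3 h the set of short-lived AU-rich transcripts stands at −1.72 and the immediate-early set at −1.62, against 0.08 for all 8447 genes.

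Finally, unstimulated cells were compared, since a response is read against its own baseline. Low interferon signalling in untreated cells keeps antiviral genes above their floor, and Lyz2, Laptm5 and C1qb are expressed by macrophages and other leukocytes, which can accompany embryonic fibroblasts in primary culture. Counts were 0 in crel-/-p65-/- (291 at an unadjusted p under 0.05), 22 in crel-/-p65-/-relb-/- (10 higher and 12 lower, 794 unadjusted), 0 in crel-/-p65-/-irf3-/- (461 unadjusted) and 0 in ifnar-/- (909 unadjusted), all in limma. In crel-/-p65-/-relb-/- cells the class I gene H2-D1 was at least 7.21-fold higher (4.11 ± 0.23, adjusted p = 0.00043), followed by Anxa8 (3.50), Vat1l (3.15), the developmental factor Barx1 (3.08) and Tnfrsf11b (2.90), which encodes osteoprotegerin. Lyz2 was at least 62.9-fold lower (−6.58 ± 0.63, adjusted p = 0.00834), Laptm5 at least 45.9-fold lower (adjusted p = 0.0299), the growth factor Ptn lower by −3.99 ± 0.30 (adjusted p = 0.00222) and Gbp3 by −2.23 (adjusted p = 0.0406). Leukocyte markers had median differences from WT of −1.81 in crel-/-p65-/-, −2.44 in crel-/-p65-/-relb-/-, −2.44 in crel-/-p65-/-irf3-/- and −0.24 in ifnar-/-. Adjusted over the list alone, 6 of 12 were lower in each of the first 3 genotypes, 2 of them called over all genes in crel-/-p65-/-relb-/-. Interferon-stimulated genes were lower in ifnar-/- cells by a median of −0.95 (adjusted p = 0.0449), with none called and 17 of 46 adjusted over the list alone, led by Gbp3 (−3.49, adjusted p = 0.1), Irgm2 (−3.45, adjusted p = 0.199) and Bst2 (−3.10, adjusted p = 0.199). In crel-/-p65-/-relb-/- and crel-/-p65-/-irf3-/- cells the median was −0.60, lost with an estimated correlation (adjusted p = 0.0693 and 0.0672; 16 and 3 lower adjusted over the list alone). Cholesterol genes were higher in ifnar-/- by 1.19 (lost with an estimated correlation, adjusted p = 0.0772; 8 of 19 adjusted over the list alone), with Nsdhl at 2.24 (adjusted p = 0.199).

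The 22 calls in crel-/-p65-/-relb-/- cells became 1 or 8 without one of that group's own arrays, 11 and 39 without the WT array of the LPS and PDGFb course and 9 without either crel-/-p65-/- array, 47 with 75th percentile scaling (12 higher, 25.5%, against 45.5%), and 381 with course as a block. In crel-/-p65-/-irf3-/- and ifnar-/- cells 1 gene passed without the WT array of the IFNb course.

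**Figure D4:**
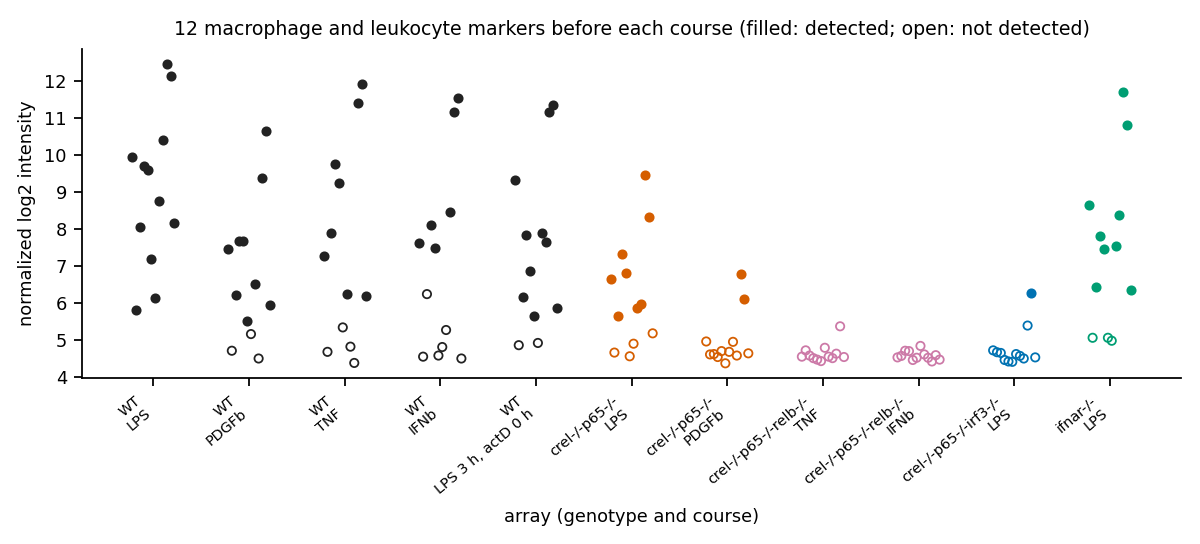
Normalized log2 intensity (y axis) of the 12 measured macrophage and leukocyte markers on the first array of each of the 11 courses (x axis), filled where detected and open where not. All 12 are detected in the WT LPS course (median 9.17), 8 in the crel-/-p65-/- LPS course (median 5.92) and none in the crel-/-p65-/-relb-/- courses (median 4.55).

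Of the 13 response lists, cell cycle, extracellular matrix, p53, glycolysis and ribosomal protein genes had no member called in any of the 16 comparisons and passed no list test with an estimated correlation (smallest adjusted p = 0.432, 0.578, 0.202, 0.275 and 0.588), although 8, 2, 3, 7 and 5 of 33 tests each passed camera's preset correlation. Adjusted over the list alone, 1 extracellular matrix gene was higher and 2 lower and 1 p53 target higher in unstimulated crel-/-p65-/-relb-/-, 1 p53 target was lower with actinomycin D, and 1 glycolysis gene was higher with IFNb and 1 in unstimulated ifnar-/-. Their medians ran from −1.96 to 1.54, from −0.38 to 0.45, from −0.43 to 0.66, from −0.64 to 0.54 and from −0.44 to 0.38. Of markers of other cell types, endothelial, epithelial, muscle, neural and adipocyte genes had 0 calls in limma over all genes (adjusted over the list alone, 1 of 5 epithelial markers was higher in unstimulated crel-/-p65-/-relb-/- and 2 in crel-/-p65-/-irf3-/-), with medians within −0.62 to 0.79, −1.10 to 0.45, −0.55 to 0.81, −0.57 to 0.59 and −0.95 to 0.93. The Y-linked gene Eif2s3y stood at 8.73 to 9.11 in crel-/-p65-/-irf3-/-, 9.24 to 9.48 in ifnar-/- and 9.84 to 10.00 in the actinomycin D course, and was not detected on the other arrays. Among these it stood at 5.23 to 6.27 in the WT IFNb course, whose dimmest detected signals were 6.16 to 6.56, and at 4.34 to 4.68 elsewhere. Male cells in the WT IFNb course, which holds 1 of the unstimulated WT arrays, are therefore not excluded. The labels do not give the sex of the embryos. Sex is therefore not separated from genotype where these knockouts are compared with WT, or crel-/-p65-/-irf3-/- with crel-/-p65-/- cells. Nor is it separated where the actinomycin D 0 h array is joined with WT LPS 3 h. Scaling to the 75th percentile moved the median of all genes by more than 0.1 in 10 of 33 contrasts (from −0.24 to 0.39), and the authors' values in 3 of 27 (from −0.13 to 0.13); the log2 changes above are those of quantile-normalized arrays.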

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

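All tests of explanations in this part were chosen after the results had been seen; the interaction tests were planned, and the check for distant arrays followed a fixed rule.

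The LPS response differed between WT and knockout cells in 34 genes for crel-/-p65-/-, 55 for crel-/-p65-/-irf3-/- and 12 for ifnar-/-, each by a test of the difference itself. The first pattern weighed is the absence of Il1b, Il1a and Tnf from the knockouts that lack c-Rel and RelA (Il1a was chosen after its values were seen). Fewer leukocytes in those cultures is a candidate source, because the differences of 12 leukocyte markers between the unstimulated WT and crel-/-p65-/- arrays of the LPS course had a median of 2.83, with WT higher. To weigh such a loss as the whole cause, the differences at 8 h were compared. The 3 cytokine genes differed from WT by 8.97, 7.27 and 7.14, more than any marker (6.33 for Fcer1g). The smallest gap of 0.81 lies within the spread bound of 2.93. Neither the cytokines nor Fcer1g were detected in the knockout at 8 h, so background limits both sides. The 2 causes, a loss of leukocytes and a need for NF-κB, cannot be told apart for these genes. In ifnar-/- cells, the marker median at 0 h was −0.24 from the mean of the WT arrays (the WT array of the LPS course stood at 1.23 from it). There the same 3 cytokine genes differed from WT at 8 h by 1.37, 1.21 and 2.59. The markers differed in that comparison by 0.24 (Lyz2) to 2.81 (C1qb), so the cytokine differences lay within their range. A direct need for NF-κB, which the design gives, stays open and untested apart from the cell mixture.

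Of the 34, 55 and 12 genes, 30, 49 and 12 did not correlate with the markers over unstimulated arrays, while 4, 6 and 0 did, against 183 of all 9180 genes. That is a count of genes and no test of the mixture, since genes near background on unstimulated arrays, such as Il1b, Il1a and Tnf, have little signal to correlate there.

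Among the 4 unstimulated WT arrays, the array of the IFNb course lay apart in 4 of 26 measures checked, where chance marks about 1 in 20 and 1.3 would be marked by chance. Its gap to the nearest array, as a share of the whole range, was 0.834 for total signal (5.80e6 against 1.40e7 to 1.56e7), 0.843 for the median level of MHC class I genes (7.58, the highest), 0.862 for glycolysis (9.84, the lowest) and 0.892 for sex-linked genes (5.34, the highest). No explanation was tested.

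In probes that have no gene in the annotation table, 28 of 1525 detected probes were called in the WT LPS response, all 28 higher (101 at an unadjusted p under 0.05), a signal in data outside the comparisons above. Which transcripts they measure is not given in the sources used here.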

How the results depend on the processing

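The tests with an additive spread, without the WT IFNb course and without genes correlated with leukocyte markers were chosen after the results had been seen; the others were planned. Arrays with a low signal over background, as in the WT IFNb and crel-/-p65-/-irf3-/- courses, limit what can be seen of dim genes, and lone arrays limit every count. No paired analysis was possible because the labels give no replicate numbers and stimulated groups hold 1 array each. Course, the only link between arrays that the labels give, was used as the source of the baseline instead. For course as a block, the block was the agent of the course and was shared by the genotypes. Slide as a block could not be run, and the authors' values gave no value for IFNb comparisons or the overlap. Where a value moved, the cause was not tested unless the setting's construction shows it.

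With the unstimulated array of the same course as baseline, which has a larger error, the counts of genes were 142 for LPS (225 as reported), 18 for TNF (50), 59 for IFNb (129), 21 for the crel-/-p65-/- difference in LPS response (34), 5 for IFNb then TNF (71) and 61 for the overlap (120). With course as a block, which leaves 2 residual degrees of freedom, they were 95, 0, 0 for PDGFb (3), 40, 6, 0 for crel-/-p65-/-irf3-/- (55), 0 for ifnar-/- (12), 0 for IFNb then TNF, 0 for actinomycin D (1), 381 for unstimulated crel-/-p65-/-relb-/- (22), 2 for unstimulated crel-/-p65-/-irf3-/- (0) and 36 for the overlap. The additive spread with own baselines gave 2 for LPS, 95 for TNF, 9 for PDGFb and 2304 for IFNb. It gave 0 for each of the 3 LPS differences, 303 for IFNb then TNF, 450 for actinomycin D and 0 for the overlap. In that fit each agent and time has the same effect in all genotypes, so real differences between genotypes count as spread. Its low counts for LPS, the LPS differences and the overlap follow in part from this construction and do not weigh against those results. The cause of the other moves was not tested.

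Scaling to the 75th percentile gave 31 for TNF, 1 for PDGFb, 8, 31 and 0 for the LPS differences of crel-/-p65-/-, crel-/-p65-/-irf3-/- and ifnar-/-, 34 for IFNb then TNF and 47 for unstimulated crel-/-p65-/-relb-/-. No filter on dim probes gave 80, 93 and 61 for the LPS differences, 5 and 4 for the TNF and IFNb differences of crel-/-p65-/-relb-/- (0 and 0), 137 for IFNb then TNF, 4 for actinomycin D, and 10, 1 and 5 for unstimulated crel-/-p65-/-relb-/-, crel-/-p65-/-irf3-/- and ifnar-/-. Probes detected on at least 10 arrays gave 148 for LPS, 0 for PDGFb, 13, 24 and 6 for the LPS differences and 33 for IFNb then TNF. Trend and robust variances gave 52, 83 and 37 for the LPS differences, 3 and 2 for the crel-/-p65-/-relb-/- differences, 2 for actinomycin D, 35 for unstimulated crel-/-p65-/-relb-/- and 1 for ifnar-/-. Joining the actinomycin D 0 h array with WT LPS 3 h gave 19, 18 and 0 for the LPS differences, 32 for IFNb then TNF and 10 for actinomycin D. No background correction gave 2 for actinomycin D. The authors' values gave 7 for the ifnar-/- LPS difference (1 of them higher, 14.3%, against 0%), 0 for actinomycin D and 1 each for unstimulated crel-/-p65-/-irf3-/- and ifnar-/-. Without the WT IFNb course, 1 gene each was called in the last 2 comparisons.

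Leaving out 1 unstimulated array at a time gave 166 to 248 for LPS, 32 to 146 for TNF, 2 to 3 for PDGFb, 75 to 214 for IFNb, 11 to 32, 28 to 51 and 0 to 15 for the LPS differences of crel-/-p65-/-, crel-/-p65-/-irf3-/- and ifnar-/-, 28 to 132 for IFNb then TNF, 0 to 1 for actinomycin D, 1 to 39 for unstimulated crel-/-p65-/-relb-/-, 0 to 1 for unstimulated crel-/-p65-/-irf3-/- and ifnar-/-, and 75 to 123 for the overlap. List tests past the threshold were 83 with an estimated correlation and 84 with fry, of 174. Rela in unstimulated crel-/-p65-/-relb-/- cells (−2.41) kept its direction in each alternative; its call was lost with the authors' values (−2.25), with no filter (−2.41) and without the WT IFNb course (−2.42), with adjusted p of 0.0832, 0.0965 and 0.075 (0.0225 to 0.272 over all alternatives), and on leaving out single arrays its value was −2.87 to −1.95. The other 217 values of these results under alternatives stayed within 1.5 times the reported count or kept their call; the crel-/-p65-/- PDGFb difference and unstimulated crel-/-p65-/- were 0 in each. Among 133 named gene results, 1951 of 2566 values under alternatives kept direction and call, 615 kept direction and lost the call, 0 turned direction, and 13 results kept their call under each alternative.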

Other observations

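All tests of explanations in this part were chosen after the results had been seen.

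Before any agent, interferon-stimulated genes were dimmer in ifnar-/- cells. The list test with an estimated correlation passed in ifnar-/- (adjusted p = 0.0449) and not in crel-/-p65-/-, crel-/-p65-/-relb-/- or crel-/-p65-/-irf3-/- (adjusted p = 0.461, 0.0693 and 0.0672), and crel-/-p65-/-irf3-/- and ifnar-/- have 1 such array each. The median level relative to the WT mean was 0.04, −0.04, 0.19 and −0.13 on the WT arrays, −0.02 and −0.25 in crel-/-p65-/-, −0.42 and −0.80 in crel-/-p65-/-relb-/-, −0.60 in crel-/-p65-/-irf3-/- and −0.95 in ifnar-/-. On the array after 3 h of LPS that began the actinomycin D course it was 0.53. The array before actinomycin D and the WT LPS 3 h array share a treatment by their labels and correlated at 0.948. Of 4 genes chosen after their values were seen, none detected in unstimulated WT cells, Saa3 stood at 3.86 and 3.80 above unstimulated WT cells on them, but Cxcl9 at 4.59 and 7.75, Tnf at 3.62 and 6.62, and Ifnb1 at 0.42 and 2.91.

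H2-D1, a class I heavy chain gene, had a level of 8.52 to 11.26 on the crel-/-p65-/-relb-/- arrays and of 4.44 to 4.76 on all others. A general rise of class I presentation genes in those cells is argued against by the other 15 measured genes of that list. Their median difference from WT was −0.43, with 12 below 0 and a highest value of 0.34. Only H2-K1, H2-T23 and H2-M3 among them are heavy chain genes. A strain variant under the probe is consistent with a change of 0.01 with IFNb at 8 h in WT, where H2-K1 changed by 2.45, while H2-D1 changed by 2.74 in crel-/-p65-/-relb-/- cells (spread of a difference 0.38). The labels give a single strain, and no sequence was examined, so this stays a hypothesis. A loss of RelB that acts on this gene alone was not tested.

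Saa3 and Chil1 had the lowest values of the 48 TNF-induced genes when TNF followed IFNb, at −3.48 and −3.27 against TNF alone at 8 h with own-course baselines. As a check on a weaker signal of the whole IFNb course, the other 46 TNF-induced genes had a median difference of 0.34 (from −2.72 to 4.15, 19 below 0). These include genes that IFNb itself induces, such as Cxcl9 (4.15), Parp14 (3.77) and Gbp5 (2.45), which raise the median. The check therefore cannot exclude a weaker course. A repression of these genes by interferon, which the design gives, may remain, and so may a difference between courses that affects single genes; neither was tested, and neither gene passed with own-course baselines (adjusted p = 0.297 for Saa3 and 0.387 for Chil1).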
